A study of Mus musculus with 6 samples.

How the data were processed

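RNA from mandibular arches of E9.5 mouse embryos of strain C57BL/6 was hybridised to 6 Affymetrix Mouse Gene ST 1.0 arrays, 3 for Tbx1+/+ (wild type) and 3 for Tbx1-/- (Tbx1 null). Per the labels' protocols, RNA was extracted with the Qiagen RNeasy Micro kit and biotin-labelled cRNA was made from 300 ng of total RNA. Per the series description, arches of 3 embryos per genotype were pooled to obtain enough RNA. The deposited values are log2 expression levels per probe set, made by the authors with RMA (background correction, normalisation between arrays and a summary per probe set) in Affymetrix Expression Console 1.1, per the submitters' processing notes. The summary level, library files and any filter are not given in the sources used here. The log2 scale was read from the values, which ran from 3.63 to 14.6 with array medians of 7.98 to 8.04 and none missing. RMA draws the arrays' distributions together, so a change shared by most genes cannot be seen in these values, and very dim or very bright probe sets tend to understate changes. The table held 0 columns of other samples.

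Probe sets were named through the platform annotation. Of 35556 probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 were unnamed there. Symbols were looked up by Entrez ID in a RefSeq gene table of assembly GRCm38.p6, which matched 21698 of the probe sets with 1 symbol and changed 0 symbols; the other 91 kept the annotation's symbol. That table was used only for names and for which genes neighbour each other. Each gene was represented by its probe set with the highest mean over the 6 arrays, which left 19938 genes, 999 of them with more than 1 probe set. Probe sets with several symbols or none entered only the fit to every probe set. No genome build is named with the values, so no positions are given.

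The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), on all 6 arrays and with no covariate, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Log2 changes are Tbx1 null minus wild type. Levels are means ± SD over 3 arrays, and fold changes are 2 to the power of the log2 change. The median SD within a genotype was 0.0728 on the log2 scale, the median SE of a change 0.0579 and its 95th percentile 0.104. Pairs of arrays were checked for identical values and none was a copy of another. No called gene had a change smaller than 0.365.

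A total of 24 gene lists was fixed before the data were examined: core mesoderm factors, the myogenic programme, heart field and cardiac muscle, mandibular neural crest mesenchyme, migratory neural crest and glia, endothelium, primitive erythroid cells, macrophages and myeloid cells, epithelium, pharyngeal endoderm, oral and surface ectoderm, neural tube and cranial neurons, Hox genes, FGF, BMP, Wnt and Hedgehog signalling, the retinoic acid pathway, p53 and cell death, cell cycle, early response genes, hypoxia and glycolysis, genes flanking Tbx1, and sex-linked genes. The last was read per array as a check of the pools, and 23 were tested. These held 509 distinct genes, of which 478 were measured by a probe set with 1 symbol; the others are not analysed here. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 23 lists. Beside it stand camera at an estimated correlation and fry, read for a shared direction unless said otherwise. Members of a list were also adjusted over the list alone.

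The genes named were set by a rule written before the data were examined: Tbx1; in each direction the 12 largest changes among genes past the threshold whose arrays do not overlap between genotypes, leaving out predicted genes, microRNA and small nucleolar RNA genes and olfactory receptors; and up to 4 members of lowest p from each list. In the higher direction 4 genes were left out by this rule (F630048H11Rik, 4930412O13Rik, Mir377 and Mir134) and 13 remained, in the lower direction 0 and 15.

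The fit was tested on simulated data with the real mean levels of 19938 genes. Their variances were drawn from the prior that limma fitted to the real arrays, and the noise was independent between genes. For Tbx1 null against wild type the fit recovered 26 of 50 genes changed 1.25-fold, 46 of 50 changed 1.5-fold and 50 of 50 changed 2-fold or 4-fold. Of 181 calls 9 (4.97%) were false. With no simulated change limma made 0 calls (1028 genes at an unadjusted p under 0.05) and camera called 0 lists (0 at an unadjusted p under 0.05). As the simulated genes were not correlated, the camera result does not show how often lists of correlated genes are called falsely.

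Alternatives fixed before the data were examined were a block on the replicate number, leaving out each array, quantile normalisation again, centring on the median, leaving out genes below the first quartile or below the median of mean level, eBayes with an intensity trend and robust estimation, array weights, the mean of a gene's probe sets, every probe set, other thresholds, and the other list tests. The mean Y-linked level as a covariate was added after seeing the data. Figures were drawn with matplotlib 3.10.9.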

Results

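Gene expression was measured in the mandibular part of the first pharyngeal arch, the embryonic tissue that forms the lower jaw and its muscles, at embryonic day 9.5 (E9.5) in C57BL/6 mice. Tbx1+/+ embryos (wild type, 3 arrays) were compared with Tbx1-/- embryos (Tbx1 null, 3 arrays). Tbx1 encodes a T-box transcription factor of the pharyngeal apparatus and lies in the region deleted in human 22q11.2 deletion syndrome. The comparison asks which transcripts of the arch depend on this gene. The deposited values are log2 expression levels per probe set, with array medians between 7.98 and 8.04, and 19938 genes were tested. Arches of 3 embryos per genotype were pooled before hybridisation. The description does not say whether each array carried a pool of its own. Y-linked transcripts differed between arrays of a genotype far beyond the median SD of 0.0728 (from 5.73 to 9.58 in Tbx1 null and from 8.57 to 9.85 in wild type, as log2 means), so the arrays of a genotype did not all carry the same pooled RNA. The p-values measure the spread between these arrays, and how much of it is technical is not known. For arrays there is no read depth, and their number limits the precision: the median SE of a log2 change was 0.0579. No control or background probes were given, so signal over background could not be judged, and levels and folds of dim probe sets, such as those of Hoxa2 and Myf5, are given with that limit.

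Tbx1 itself (probe set 10438347, Entrez gene 21380) fell from a log2 level of 11.44 ± 0.18 (SD, n = 3) in wild type to 9.48, 9.39 and 9.63 (SD 0.12, n = 3) on Tbx1 null replicates 1, 2 and 3. This is a log2 change of -1.94 (95% confidence interval -2.16 to -1.71), or 3.83-fold lower, with a limma adjusted p = 0.000684. The wild-type arrays lay between 11.31 and 11.64, so the genotypes did not overlap. Which part of the gene the null allele lacks, and where in it the probes lie, is not given in the sources used here, so the remaining signal can include transcript from undeleted parts.

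Besides Tbx1, the largest decreases among genes past the threshold were of Lhx2 and Slit1. Lhx2, a LIM-homeodomain transcription factor of the arch's core mesoderm (probe set 10471833, Entrez gene 16870), fell from 9.83 ± 0.11 to 8.26 ± 0.14, 2.96-fold lower (log2 change -1.56, SE 0.08, limma adjusted p = 0.000784). Slit1, a secreted guidance ligand of Robo receptors (probe set 10467599, Entrez gene 20562), fell from 9.002 ± 0.060 to 7.635 ± 0.071, 2.58-fold lower (log2 change -1.37, SE 0.05, limma adjusted p = 0.00025). The next largest decrease among the called genes was of Apod, a lipocalin, 1.70-fold lower. The largest increase among genes past the threshold was of Rxfp1, the relaxin receptor, which rose from 8.67 ± 0.11 to 9.53 ± 0.11 (1.82-fold, adjusted p = 0.0133). Tbx20, a T-box factor of the heart, followed, rising from 7.77 ± 0.12 to 8.45 ± 0.12 (1.60-fold, adjusted p = 0.0422).

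In all, 32 genes passed a limma adjusted p of 0.05, 0.16% of those tested. Of these, 17 were higher and 15 lower in Tbx1 null. After another round of quantile normalisation the same test called 12 higher and 22 lower. At an unadjusted p under 0.05 there were 1097 higher and 786 lower genes, a balance that turned to 899 higher and 1419 lower after quantile normalisation again and to 931 higher and 1081 lower after centring each array on its median. Among the 12146 probe sets with no gene name, 1142 were higher and 284 lower at that threshold, and 0 passed an adjusted p of 0.05. In the values as deposited, 15.4% of genes had no overlap between the arrays of the genotypes, against the 10% that chance gives for 3 against 3. The smallest change called was 0.37 on the log2 scale. Ngfr, the low-affinity neurotrophin receptor carried by neural crest cells, had a log2 change of -0.70 (SE 0.06, adjusted p = 0.0142). Gfra1, the co-receptor of glial cell line-derived neurotrophic factor, changed by -0.75 (SE 0.08, adjusted p = 0.0294), and Ntn1, the axon guidance ligand netrin 1, by -0.61 (SE 0.07, adjusted p = 0.0422). The Notch target Heyl changed by -0.73 (SE 0.06, adjusted p = 0.0133) and the retinoid X receptor Rxrg by -0.68 (SE 0.08, adjusted p = 0.0422). Car2 (carbonic anhydrase), Eif4a3 (a helicase of the exon junction complex) and Lypd1 fell by 0.69, 0.56 and 0.55 on the log2 scale. Eif4a3 has a near-identical copy, Eif4a3l1, so its probe set may read both.

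Among the other genes that rose, Insyn2b rose by 0.62 (SE 0.04, adjusted p = 0.00507), Meg3, the maternally expressed long non-coding RNA of an imprinted domain, by 0.47 (SE 0.04, adjusted p = 0.0142), and Meis1, a TALE homeodomain factor, by 0.46 (SE 0.05, adjusted p = 0.0374). The imprinted zinc-finger gene Plagl1 rose by 0.40 and Msx2, a homeobox gene induced by BMP, by 0.39 (adjusted p = 0.0305 and 0.0422). The receptor tyrosine kinase adaptors Dok5 and Dok4 rose by 0.48 and 0.37, and Lrrc32, Fam83f and Ano3 by 0.40, 0.38 and 0.37. Tbx1, Lhx2 and Slit1 passed the threshold with any of the 6 arrays left out, and no other called gene did. The count of 32 became 13, 3 and 20 without wild type replicates 1, 2 and 3, and 3, 3 and 10 without Tbx1 null replicates 1, 2 and 3.

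**Figure D1:**
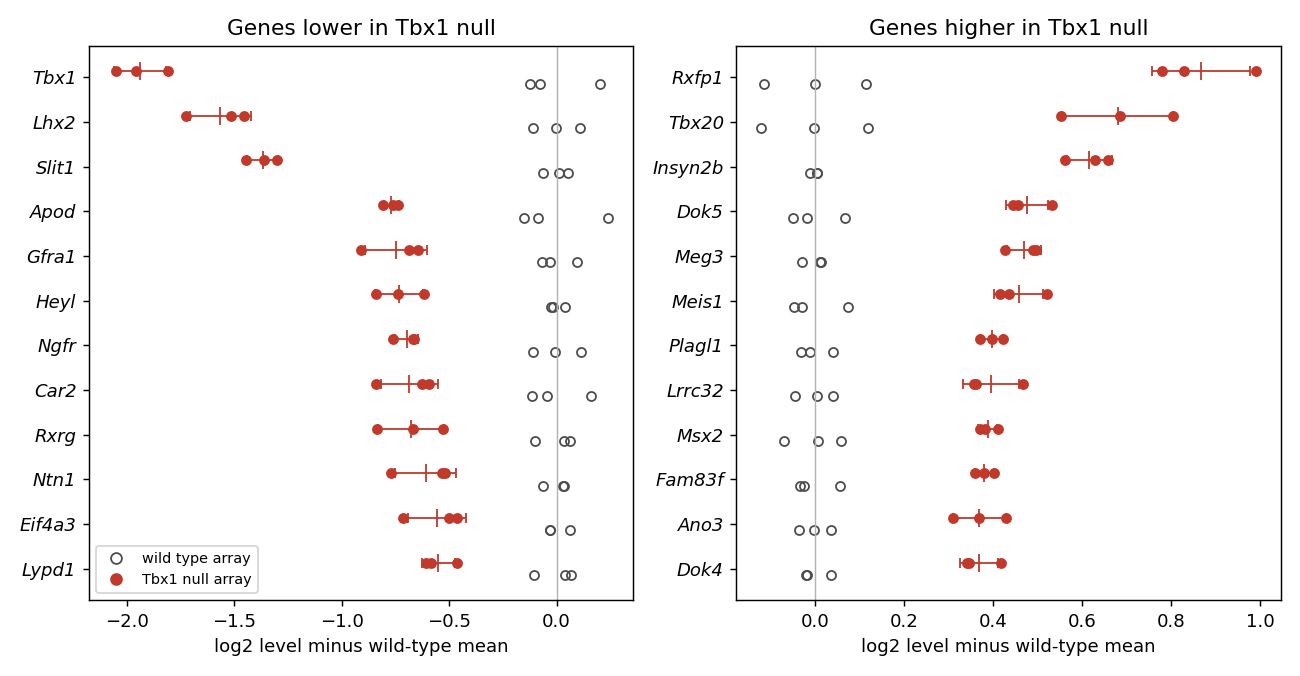
Log2 level of the 24 named genes on each array, set against the wild-type mean of that gene (x axis, log2; 12 genes lower in Tbx1 null on the left, 12 higher on the right). Open circles are the 3 wild-type arrays and filled circles the 3 Tbx1 null arrays, with the mean and SD of the latter as bars; Tbx1, Lhx2 and Slit1 lie at -1.94, -1.56 and -1.37.

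Gene lists fixed before the data were examined were tested with camera at a preset correlation, and 8 of 23 passed. With a correlation estimated per list 1 passed, BMP signalling, and with fry's directional test 2 passed, BMP signalling and primitive erythroid cells. The mixed test of fry, which lets members go either way, passed more lists. Among them were core mesoderm factors, Wnt signalling and genes flanking Tbx1 (fry mixed adjusted p = 0.000188, 0.000188 and 0.0053). Endothelium and epithelium did not pass it (0.497 and 0.223). Counts of members below are adjusted over the list alone unless said otherwise. In each of the 16 lists with a median between -0.05 and 0.05, leaving out 1 array moved the median by over 1.5 times or turned its sign, the latter in 7.

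BMP signalling genes were higher in Tbx1 null. Of 24 measured members 15 rose, 1 fell and 8 did not pass, with a median log2 change of 0.21 (camera adjusted p = 2.63e-11; adjusted p = 0.0339 with an estimated correlation; fry adjusted p = 0.00225). Msx2 was the only member past the threshold over all genes. The ligand Bmp4 rose from 11.63 ± 0.03 to 11.95 ± 0.05 (log2 change 0.32), the T-box gene Tbx3 by 0.43 and the receptor-regulated Smad9 by 0.37. Members that restrain BMP signalling went both ways: the inhibitory Smad7 and Smad6 rose by 0.35 and 0.27 and the pseudoreceptor Bambi by 0.42, while Grem1, a secreted BMP antagonist, fell from 8.49 ± 0.21 to 7.94 ± 0.06. Of the list, 7 members also stand on other lists.

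The heart field and cardiac muscle list was also higher. Of 27 measured members 14 rose, 0 fell and 13 did not pass, and 23 lay above 0. The median log2 change was 0.26 (camera adjusted p = 2.63e-11; adjusted p = 0.174 with an estimated correlation; fry adjusted p = 0.0649). Tbx20 was the only member past the threshold over all genes. Tbx3 rose by 0.43, the muscle methyltransferase gene Smyd1 from 7.77 ± 0.14 to 8.40 ± 0.20 and Pln, the phospholamban gene of heart muscle, by 0.33. Of its members, 11 stand on other lists too.

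Core mesoderm factors, the transcription factors of the arch's muscle progenitors, did not move together. Of 16 measured members 1 rose, 4 fell and 11 did not pass (median -0.02, camera adjusted p = 0.169; adjusted p = 0.615 with an estimated correlation). Besides Lhx2, the members that fell were Ebf2 by 0.54, Tcf21 by 0.53 and the growth factor gene Fgf10 by 0.22, while Isl1 rose from 10.17 ± 0.17 to 10.53 ± 0.13. No member rose without wild type replicate 3 or without any 1 of the Tbx1 null arrays, 3 did without wild type replicate 1 and 2 without wild type replicate 2. Lhx2 was the only member past the threshold over all genes, and it alone fell without wild type replicate 3 or Tbx1 null replicate 1 or 2. The list passed without wild type replicate 2 (adjusted p = 0.042) and without Tbx1 null replicate 3 (adjusted p = 0.0401).

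Myogenic programme genes changed in both directions. Myf5, the first myogenic regulatory factor of the arch, fell from 7.63 ± 0.13 to 6.97 ± 0.14, 1.58-fold lower, with an adjusted p of 0.0509 over all genes and 0.00299 over the list alone. Actc1, the cardiac actin gene, went the other way, from 9.603 ± 0.385 to 11.001 ± 0.584. In all 4 of 31 members rose (Actc1, Smyd1, Ttn and Tnni1) and 3 fell (Myf5, Chrna1 and Tnnt1). Smyd1 and Ttn also stand on the heart field and cardiac muscle list, where Myl7 rose by 0.84. Tnnt2 stands on both lists with a change of 0.62. Its limma p adjusted over the list alone passed on the heart list (0.0298) but not on the myogenic list (0.0514). The median was -0.02, the mean 0.10 and camera's direction up, with an adjusted p of 0.580. Without wild type replicate 2 or 3 only 1 member rose, and without Tbx1 null replicate 1 8 did. The count without wild type replicate 1 was 5, and without Tbx1 null replicates 2 and 3 it was 2 each. Only 1 member fell without wild type replicate 1 or 2 or Tbx1 null replicate 3.

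Mandibular neural crest mesenchyme, the connective tissue and skeletal progenitors of the arch, changed in both directions. Of 33 measured members 7 rose, 3 fell and 23 did not pass, with a median of 0.07 (camera adjusted p = 0.00517; adjusted p = 0.475 with an estimated correlation). Meis1 and Msx2 passed over all genes. Prrx2 rose from 12.27 ± 0.01 to 12.50 ± 0.02 and Hand1, a bHLH factor of the distal arch, from 9.75 ± 0.12 to 10.25 ± 0.20. The members that fell were Tfap2b by 0.63, Foxc1 by 0.41 and Gsc by 0.22. No member fell without Tbx1 null replicate 1, where 4 rose. The counts were 4 and 1 without Tbx1 null replicate 2, 8 and 1 without wild type replicate 3 and 7 and 5 without wild type replicate 1, and the median was 0.12 without wild type replicate 2. The list did not pass without wild type replicate 1 (adjusted p = 0.241).

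Oral and surface ectoderm markers also changed in both directions: 5 of 20 measured members rose and 1, Tfap2b, fell (median 0.02, camera adjusted p = 0.0177; adjusted p = 0.232 with an estimated correlation). Pitx1 rose by 0.33, the basal keratin Krt14 from 9.51 ± 0.16 to 9.94 ± 0.07 and Trp63, the p63 gene of basal epithelium, by 0.23. The list did not pass without wild type replicate 2, wild type replicate 3 or Tbx1 null replicate 1 (adjusted p = 0.0532, 0.0758 and 0.0837), and no member fell without wild type replicate 3 or Tbx1 null replicate 1 or 2. Its median was 0.01 without Tbx1 null replicate 1 and 0.05 without wild type replicate 1, wild type replicate 2 or Tbx1 null replicate 3. Markers shared by all epithelia had 23 of 25 members above 0 and a median of 0.12 (camera adjusted p = 1.91e-05; adjusted p = 0.410 with an estimated correlation). None of them passed by itself, with 4 higher and 0 lower at an unadjusted limma p under 0.05; Krt8 had a log2 change of 0.24 and Krt18 of 0.17. Without wild type replicate 2 the median was 0.05, and without Tbx1 null replicate 3 it was 0.07.

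Primitive erythroid genes, the markers of the first blood cells, were lower in Tbx1 null. Of 16 measured members 15 fell, and the remaining one, Slc25a37, had a change of -0.14. The median was -0.22 (camera adjusted p = 1.6e-16; adjusted p = 0.0644 with an estimated correlation; fry adjusted p = 0.00803). The anion exchanger gene Slc4a1 fell from 10.51 ± 0.08 to 10.11 ± 0.06, the erythroid factor Klf1 by 0.37, Gata1 by 0.32 and Rhag by 0.37. No member passed over all genes. The other markers of blood and vessel cells gave no call: none of 30 endothelial genes (0 higher and 3 lower at an unadjusted limma p under 0.05; median -0.03, camera adjusted p = 0.136) and none of 16 macrophage and myeloid genes (1 higher and 2 lower at an unadjusted p under 0.05; median -0.03, camera adjusted p = 0.169). Without Tbx1 null replicate 3 the endothelial list passed as lower (adjusted p = 0.000467).

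Among migratory neural crest and glial markers Ngfr fell and the other 13 members did not pass (median -0.04, camera adjusted p = 0.426). With wild type replicate 1 left out 2 members rose and 2 fell, and the median turned to 0.02, as it did without Tbx1 null replicate 2. With wild type replicate 2 left out 2 fell, and the median was -0.12, as it was without Tbx1 null replicate 3. Sox10, the transcription factor of migrating crest and glia, had a log2 change of -0.85 with an SE of 0.31, and its wild-type arrays varied widely (9.41 ± 0.71 against 8.57 ± 0.19). Neural tube and cranial neuron genes had 19 of 26 members below 0 and a median of -0.09 (camera adjusted p = 0.00633; adjusted p = 0.550 with an estimated correlation). None of these passed by itself, with 1 higher and 6 lower at an unadjusted limma p under 0.05. Pax6 had a change of -0.22 and Nefl of -0.30, while Dcx, the 1 that was higher, had a change of 0.16. The list did not pass without wild type replicate 1 (adjusted p = 0.213, median -0.05) or Tbx1 null replicate 1 (adjusted p = 0.0837), and 5 members fell without wild type replicate 2.

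Of 15 Hox genes, which the mandibular arch as a rule lacks, 2 rose. Hoxa2, the selector gene of the second arch, rose from 6.70 ± 0.16 to 7.81 ± 0.46, 2.15-fold, and Hoxb2 by 0.63 from 8.37 ± 0.14, 1.54-fold. Their adjusted p-values over all genes by limma were 0.126 and 0.0577, so neither passed there. Which cells of the dissected tissue carried these transcripts was not tested. The list median was 0.02 (camera adjusted p = 0.426), and Hoxd4 and Hoxa5 had changes of -0.14 and -0.12. Pharyngeal endoderm genes gave 1 increase among 20 members, Fgf15 (log2 change 0.27), and a median of 0.04 (camera adjusted p = 0.130); the list passed without wild type replicate 1 or Tbx1 null replicate 1 (adjusted p = 0.019 and 0.0194). Of its members 3 rose without wild type replicate 1 (median 0.08) and 0 without wild type replicate 3 or Tbx1 null replicate 1 (median 0.06 and 0.09), and 1 fell without wild type replicate 2 or Tbx1 null replicate 3.

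Hedgehog signalling genes had 11 of 14 members above 0 and a median of 0.12 (camera adjusted p = 0.00934; adjusted p = 0.410 with an estimated correlation). None passed by itself, with 2 higher and 0 lower at an unadjusted limma p under 0.05, among them Gli2 with a change of 0.16. Without wild type replicate 1 the list did not pass (adjusted p = 0.211, median 0.07). The FGF signalling list was not called: Fgf15 rose, and Fgf10, Etv1 and Dusp6 fell by 0.22, 0.18 and 0.18, each by a small amount. Its median was 0.0082 and its mean -0.0092 (camera adjusted p = 0.914, direction down). In 5 of the 6 fits with an array left out no FGF member passed, and without Tbx1 null replicate 2 Fgf15 alone did. Wnt signalling had 3 members that rose (Bmp4, Dkk1 and Rnf43) and 2 that fell (Nkd2 and Sfrp2), with a median of 0.05 (camera adjusted p = 0.169). The counts were 6 and 4 without Tbx1 null replicate 3 (median 0.07), and the median was 0.01 without Tbx1 null replicate 1. No retinoic acid pathway gene passed (2 higher and 0 lower at an unadjusted limma p under 0.05). Their median was 0.04, their mean -0.0026 and camera's direction up (adjusted p = 0.381).

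Lists on cell state moved little. None of 34 cell cycle genes passed (0 higher and 0 lower at an unadjusted limma p under 0.05), and their median was -0.04 (camera adjusted p = 0.0651). The cell cycle list passed as lower without wild type replicate 1 or 2 or Tbx1 null replicate 3 (adjusted p = 0.019, 0.0494 and 0.0401). Among p53 and cell death genes Trp53inp1 rose by 0.41 and the list did not pass (median 0.03, camera adjusted p = 0.366); no member passed without wild type replicate 2 or 3 or Tbx1 null replicate 2 or 3. Among early response genes, which rise during tissue handling, Ccn2 fell by 0.31 and the list did not pass (median -0.05, camera adjusted p = 0.135); no member passed without any 1 of the wild-type arrays or Tbx1 null replicate 1 or 2, and 2 fell without Tbx1 null replicate 3. No gene of hypoxia and glycolysis passed (1 higher and 1 lower at an unadjusted limma p under 0.05; median -0.04, camera adjusted p = 0.231), though the list did without wild type replicate 2 or Tbx1 null replicate 3 (adjusted p = 0.00144 and 0.0462). The 20 measured genes that flank Tbx1 held none past the threshold (0 higher and 2 lower at an unadjusted limma p under 0.05), and all lay between -0.16 and 0.11. Their median was 0.02, their mean -0.00069 and camera's direction up (adjusted p = 0.914).

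Among the members named, Smad6, Smad7, Bambi, Grem1, Tcf21, Ttn, Tnni1, Chrna1, Myl7, Tnnt2, Tfap2b, Foxc1, Gsc, Slc25a37 and Dkk1 fell outside the fixed rule and were chosen after their values were seen.

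**Figure D2:**
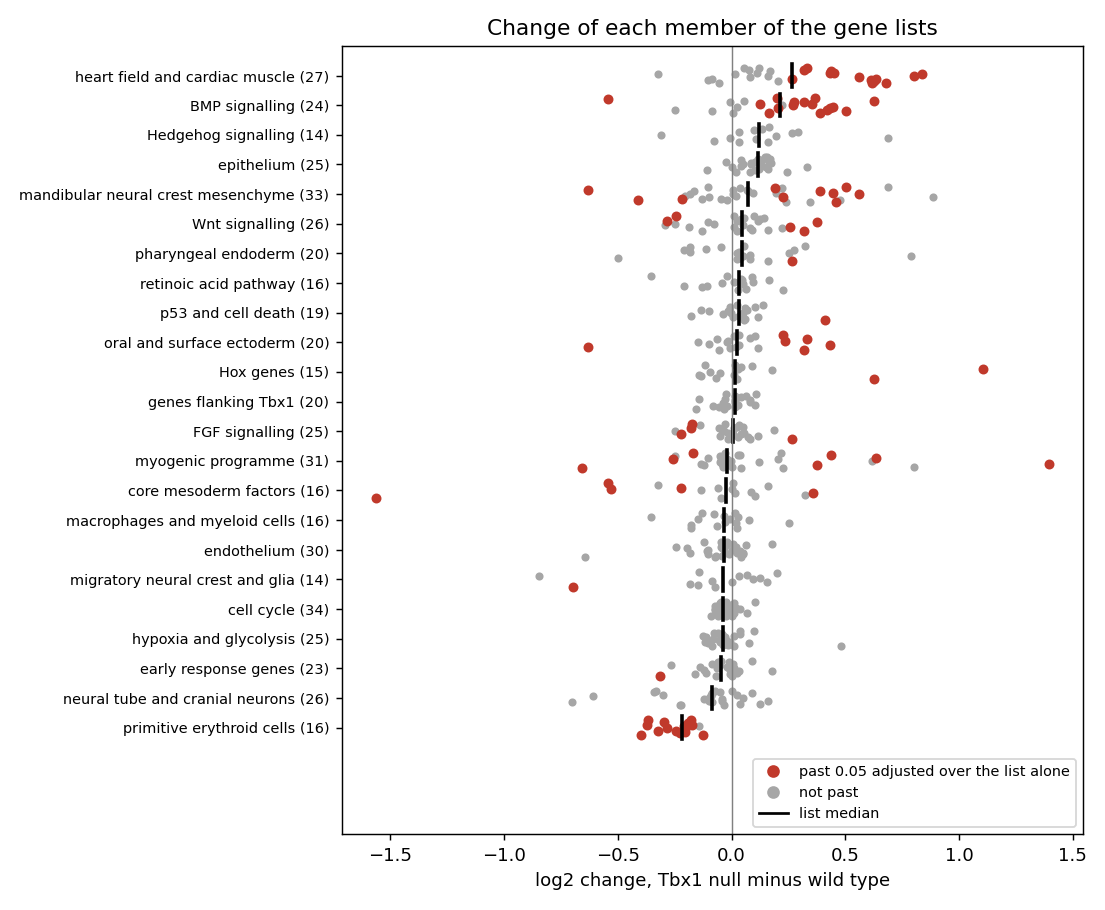
Log2 change, Tbx1 null minus wild type (x axis), of each measured member of the 23 gene lists (y axis, with the number of members), where red points passed 0.05 adjusted over the list alone and black bars are list medians. The medians run from -0.22 for primitive erythroid cells to 0.26 for the heart field and cardiac muscle list.

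The arrays also differed in sex-linked transcripts. The mean log2 level of the Y-linked genes Eif2s3y, Kdm5d and Uty was 8.57, 9.07 and 9.85 on wild type replicates 1, 2 and 3 and 9.58, 9.28 and 5.73 on Tbx1 null replicates 1, 2 and 3. Xist, transcribed from the inactive X chromosome of females, was at 12.7, 12.5 and 11.9 in wild type and 12.4, 12.6 and 13.1 in Tbx1 null. Tbx1 null replicate 3 thus had the lowest Y-linked and the highest Xist level. On that array the median of heart field and cardiac muscle genes lay 0.38 above the wild-type mean, against 0.15 and 0.23 on Tbx1 null replicates 1 and 2. For BMP signalling genes the corresponding medians were 0.29, 0.16 and 0.18, and for epithelial genes 0.21, 0.07 and 0.06.

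**Figure D3:**
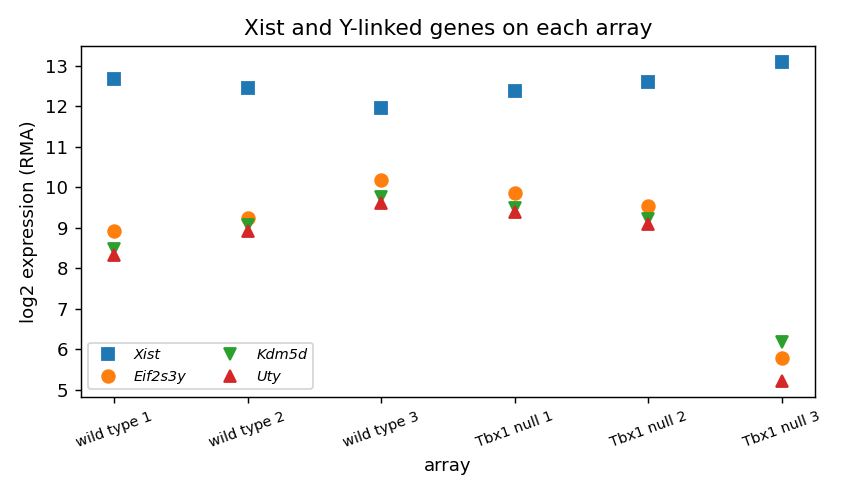
Log2 expression (y axis) of Xist and of 3 Y-linked genes on each of the 6 arrays (x axis), 1 point per gene and array, without averaging. The Y-linked genes average 5.73 on Tbx1 null replicate 3 and between 8.57 and 9.85 on the other arrays.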

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

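The Y-linked covariate was chosen after seeing the data; the other alternatives were set beforehand. The Tbx1 log2 change stayed past the threshold in each of the 16 alternative fits, between -2.00 and -1.84 and an adjusted p of at most 0.0146. All 32 called genes kept their direction wherever they were tested.

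The count of genes past the threshold was 32 (17 genes higher in Tbx1 null, 15 genes lower in Tbx1 null). It was 34 to 38 with quantile normalisation again (27 of the 32 kept), centring, either filter on dim genes or the mean of probe sets. It rose to 96 (57 higher, 39 lower) with an intensity trend and robust estimation, and to 334 (226 higher, 108 lower) with array weights, which counted wild type replicate 2 most, at 3; both kept the 32, and the cause was not tested. It fell to 4 (1 higher, 3 lower) with every probe set, where more features were tested and eBayes was fitted to all of them. The genes tested in the main fit then gave 966 higher and 676 lower at an unadjusted limma p under 0.05, against 1097 and 786. The number of features was thus not the only difference. With the Y-linked level as covariate the count fell to 18 (7 higher, 11 lower) and 13 of the 32 were kept. That fit loses a residual degree of freedom. Other thresholds gave 89 (50 higher, 39 lower) at an adjusted p under 0.10, 15 (5 higher) with 1.5-fold added, and 62 (33 higher, 29 lower) at an unadjusted p under 0.05 with 1.5-fold. With an array left out, the count ranged from 3 to 20, with 0 to 12 higher and 3 to 10 lower; fewer arrays were tested. Where 0 were higher by limma, 805 to 912 genes were higher at an unadjusted p under 0.05.

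The labels do not say whether the replicate number pairs the arrays, and 6 arrays are too few to settle it. Deviations of same-numbered arrays from their group means had correlations of -0.045, 0.26 and 0.149. Among arrays of the other genotype, 4 of 6 arrays correlated best with their own number. With the replicate number as a block the count was 6 (2 higher, 4 lower), and 7 lists passed, oral and surface ectoderm being lost (adjusted p = 0.0799).

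The count of gene lists past the threshold was 8. It was 1 with a correlation estimated per list and 2 with fry, 6 to 10 in the other fits, and 7 to 12 with an array left out. BMP signalling, heart field and cardiac muscle, primitive erythroid cells and epithelium passed in each fit at the preset correlation. At that correlation they also passed in 3, 4, 5 and 5 of the splits of the arrays, given below, that are not the genotype. Epithelium alone of these had a lower camera adjusted p in such a split (2.34e-07 against 1.91e-05). Hedgehog signalling and neural tube genes did not pass with array weights (adjusted p = 0.113 and 0.0787) or with genes below the median level left out (0.0536 and 0.0565); core mesoderm factors (0.033) and endothelium (0.00157) passed with the Y-linked covariate, and Hox genes, with 2 members left, among genes above the median (0.0114). Cell cycle genes passed as lower with centring (0.0221), with genes below the first quartile (0.0354) or the median (0.0114) left out, and without wild type replicate 1 or 2 or Tbx1 null replicate 3 (0.019, 0.0494 and 0.0401).

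Among 103 other named genes, 23 of them called, none changed direction. Of their values under alternatives 1402 stayed on their side of the threshold, 166 lost the call and 43 gained it. The 1402 include values of uncalled genes that stayed uncalled. All 166 losses fell on the 23 called genes, and 107 of these losses came with an array left out. A further 20 came with every probe set, 18 with the replicate number as a block and 15 with the Y-linked level as covariate.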

Other observations

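All tests in this part were chosen after the results were seen, with 2 exceptions. These are the splits of the arrays and the comparisons of the heart field and primitive erythroid lists with matched random lists. The imprinted domain was not a fixed list and was picked after its values were seen, so its tests count as chosen afterwards. Genes and sets named here were picked after their values were seen.

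The imprinted domain between Dlk1 and Dio3, which carries paternally expressed protein-coding genes and maternally expressed non-coding RNAs, was higher in Tbx1 null along most of its length. Of 48 measured genes 45 lay above 0, 32 passed adjusted over the domain alone as higher and 0 as lower, and the median log2 change was 0.30. As neighbours in 1 domain, 40 of them microRNA genes, they are not independent readings, so these counts overstate the support. Some were dim, such as Mir376a at 4.55 in wild type, where signal over background could not be judged. Over all genes Meg3, Mir377 and Mir134 passed (log2 changes 0.47, 0.64 and 0.45). The paternally expressed Dlk1 rose from 13.20 ± 0.08 to 13.50 ± 0.08 and Rtl1 by 0.23, the maternally expressed Rian by 0.35, while Dio3 at the far end had a change of -0.02. The 40 microRNA genes of the domain had a median of 0.32 and its 8 other genes one of 0.26. Of 42 imprinted genes elsewhere in the genome 2 passed over that list alone, Plagl1 at 0.40 and Zim1 at 0.42, and their median was 0.03, with 26 above 0 and 8 higher and 4 lower at an unadjusted limma p under 0.05. This median, though small, lay at percentile 99.9 of random lists matched on level. Members of the random lists were drawn independently, so the percentile takes no account of genes that vary together and does not establish a shared rise.

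Acta2, smooth muscle actin, was at 10.24 ± 0.37 in wild type and 11.33 ± 0.21 in Tbx1 null (adjusted p = 0.0865), and Myocd, the myocardin gene, at 8.24 ± 0.14 and 8.87 ± 0.19 (adjusted p = 0.0942). Six2 and Smoc1 had log2 changes of -0.78 and -0.91 (adjusted p = 0.0577 and 0.0675), and Cdh19, a cadherin of crest-derived glia, of -0.68 (adjusted p = 0.437). The forkhead genes Foxe3 and Foxd2, with 1 annotated gene between them, both fell, by 0.53 and 0.44 (limma adjusted p = 0.0133 and 0.0466).

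Heart field and cardiac muscle genes were higher in Tbx1 null with camera at the preset correlation, but not with an estimated correlation (adjusted p = 0.174) or fry (adjusted p = 0.0649). A trend of the values with signal level was argued against, as the list median was at percentile 100 of 10000 random lists matched on level, whose middle 95% ran from -0.04 to 0.03. The sex make-up of the pools as the whole cause was also argued against, as the median stayed at 0.19 without Tbx1 null replicate 3. Heart muscle carried along in the dissection could not be excluded. Of 12 members grouped as contractile 6 rose, among them Myl7 (8.54 to 9.37) and Tnnt2 (8.64 to 9.26). The group held Smyd1, Pln and Ryr2 beside genes of the contractile filaments, and Smyd1 and Pln were among the 6. Its median was lower than that of 10 regulators (difference -0.27), 7 of which rose. The group was also dimmer (median level 7.65 against 9.77 in wild type), and dim probe sets tend to understate changes. A change of gene activity in the Tbx1 null arch may account for the regulators, and stays open as a hypothesis beside heart muscle carried along.

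Primitive erythroid genes were lower with camera at the preset correlation and with fry, but not with an estimated correlation (adjusted p = 0.0644). Fewer blood cells in the Tbx1 null pools could not be told apart from lower activity of these genes. In all 16 of 16 members lay below 0, a count that the call had already fixed. Those of highest signal were Hba-x, Hbb-y and Hbb-bh1 (13.5, 13.5 and 13.2 in wild type, with log2 changes of -0.20, -0.17 and -0.21). Of the members 1, Tal1, also marks endothelium. A trend with signal level was argued against by a median at percentile 0 of matched random lists, and the sex make-up of the pools by a median of -0.20 without Tbx1 null replicate 3. Whether blood was lower in the embryos or was lost in the dissection was not tested.

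For the Dlk1 to Dio3 domain, a shift of small RNA probe sets on the arrays was argued against as the whole cause, since 260 microRNA genes outside it had a median of 0.0086, although 25 of them were higher and 4 lower at an unadjusted limma p under 0.05. The unnamed probe sets were also higher more often than lower at that threshold (1142 against 284), so a smaller shift as part of the cause is not excluded. A trend with signal level was argued against by a median at percentile 100 of matched random lists (middle 95% from -0.03 to 0.02), and sex make-up by a median of 0.30 without Tbx1 null replicate 3. A higher activity of the whole domain, or a larger share of cells that express it, may account for the pattern; neither was tested.

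The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 32 genes (17 higher, 15 lower), and the highest of the other splits gave 0 by limma (226 to 1665 genes at an unadjusted p under 0.05, against 1883), so 1 of 10 splits reached the real count for all genes and for each direction. For lists at the preset correlation the real split gave 8 and the highest other 11, with wild type replicate 1 and Tbx1 null replicates 2 and 3 set against the rest, and 3 of 10 splits gave at least 8. List calls at that correlation thus also follow a structure of the arrays that is not the genotype. The median of the real split was larger than in the other 9 for BMP signalling (0.21 against at most 0.10), primitive erythroid cells (0.22 in size against at most 0.12) and heart field and cardiac muscle (0.26 against at most 0.22), and, of the other called lists, for Hedgehog signalling (0.12 against at most 0.08) and neural tube genes (0.09 in size against at most 0.07). For epithelium (0.12 against 0.13), mandibular neural crest mesenchyme (0.07 against 0.10) and oral and surface ectoderm (0.02 against 0.06) another split gave a larger one. By camera at the preset correlation, neural tube genes also passed in 5 of the other 9 splits and Hedgehog signalling in 2. Their lowest camera adjusted p there was 8.72e-05 and 0.00114, below the 0.00633 and 0.00934 of the real split. For these 2 lists the call is thus not particular to the genotype.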
